A study of Homo sapiens with 18 samples.

How the data were processed

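Poly(A) RNA was sequenced from 18 cultures of 2 human prostate cancer cell lines, each under 3 conditions with 3 biological replicates. C4-2 is a castration-resistant line derived from LNCaP cells, and MDA-Pca-2b is an androgen-sensitive line. Cultures were held at 7 mM glucose for 24 h, at 25 mM glucose for 24 h, or in 500 µM methylglyoxal for 3 h. Methylglyoxal is a reactive dicarbonyl that forms as a by-product of glycolysis and adds to proteins and DNA. Per the labels, the lines were grown in different media, and the MDA-Pca-2b medium also held growth supplements such as epidermal growth factor, insulin and hydrocortisone. Line and medium therefore cannot be separated. The methylglyoxal cultures differ from both glucose groups in exposure time as well, and the labels do not give the glucose level of their medium. The labels call the replicates biological but name no batch or day, so p-values measure only the spread between these cultures, part of which may be technical.

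The authors deposited 1 table of raw read counts per gene, with whole numbers for 32439 genes in 18 columns. Per the submitters' processing notes, fastp 0.23.2, HISAT2 and the GRCh38 genome were used on the reads. The counting program, the annotation release and the strand setting are not given in the sources used here. Of the gene identifiers, 32411 are in GENCODE release 44 and 32270 have the identical chromosome, start and end (99.56%), so coordinates are those of GRCh38 as the table gives them. Every column was matched to a sample by its library name. The description of the third MDA-Pca-2b culture at 7 mM glucose repeats a C4-2 library name, and its title was used to place it. The cell line tag counts upward over the C4-2 replicates, while their titles name C4-2 throughout, and the titles were followed. Total counts per library ran from 18237752 to 26637732. A floor of 3 counts corresponded to 0.112 to 0.161 CPM in a single library. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

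Tests were computed from the deposited counts in R 4.3.3. Genes passing edgeR's filterByExpr (17503) were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood models of 6 group means, with all 18 libraries sharing 1 estimate of the spread (12 residual degrees of freedom, 13.9 prior degrees of freedom, common biological coefficient of variation 5.9%). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. The comparisons were methylglyoxal against 7 mM glucose and 25 mM against 7 mM glucose within each line, the difference of each effect between the lines (an interaction contrast, C4-2 minus MDA-Pca-2b), and C4-2 against MDA-Pca-2b at 7 mM glucose. Levels are TMM-scaled CPM, given as the mean ± SD of 3 libraries. Fold changes are log2 values of the fit with a standard error (SE) and a prior count, which shrinks or inflates changes of genes near 0. A median log2 fold change over all genes tested lay between -0.031 and 0.008 in every comparison.

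The comparisons, tests, filter, lists, rule for named genes and first set of alternatives were fixed before the data were examined. Any alternative or test added later is named where it is used. The 28 gene lists cover stress responses, metabolism, the cell cycle, androgen response, abundant housekeeping transcripts and markers of prostate and other cell types; 9 of their genes are absent from the table. List tests used camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison. Counts adjusted over the list alone are given where they differ from those over all genes. Camera with an estimated correlation and fry were run as alternatives.

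The rule named the 5 largest rises and falls of each treatment comparison among called genes of at least 5 CPM whose replicates did not overlap. It also named up to 3 called members of each list of at least 1 CPM, the 5 largest differences in each direction of the interaction and line comparisons, and GLO1, HAGH, PARK7, AKR1B1, HMOX1, TXNIP, ATF3, HSPA1A and KLK3 in every comparison. Some genes named by the rule are not reported here. AKR1B1 did not pass the filter on low counts. Groups of 3 against 3 do not overlap in 10% of splits by chance. The rule gave 221 different genes, of which 118 are printed. This subset was chosen after values were seen and leaves out mostly further members of the same lists. The printed numbers are 48 of 76, 51 of 78 and 32 of 71 for methylglyoxal in C4-2, in MDA-Pca-2b and for the difference, 4 of 11, 6 of 13 and 2 of 9 for 25 mM glucose in the same order, and 33 of 99 between the lines. Further genes named for the closing section were chosen after their values were seen.

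Gene and list calls were tested on counts simulated from the real means and library sizes, with 200 genes changed. For 1.5-fold changes the share recovered was 74.6% for methylglyoxal in C4-2 (17216 genes) and 85.1% in MDA-Pca-2b (17198 genes). It was 77.6% and 80.6% for 25 mM glucose (17246 and 17211 genes), 62.7% and 61.2% for the 2 differences in this order (17158 and 17227 genes) and 74.6% between the lines (17160 genes). For 4-fold changes the lowest share was 89.4%, for the difference of the glucose effects. Groups with an outlying library may give lower shares. False calls numbered 5 to 16.

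Alternatives were scaling by RLE, no filter, at least 1 CPM in 3 libraries, a minimum log2 fold change of 1, a replicate block, fits of 1 line or of only the libraries compared, DESeq2 1.42.0, the 25 mM libraries as the control of methylglyoxal, the lines compared at 25 mM glucose and each replicate left out in turn. Alternatives planned for a table without counts were not run. Exploratory tests of 1302 Gene Ontology terms used the same camera settings in 6 comparisons and were added after the data were seen.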

Results

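The 18 libraries come from 2 prostate cancer lines, C4-2 and MDA-Pca-2b, at 7 mM glucose, at 25 mM glucose and after methylglyoxal, with 3 cultures each. Of the 32439 genes in the table, 17503 had enough counts to be tested. In each line the first principal component set the methylglyoxal libraries apart from both glucose groups. It held 55.1% of the variance in C4-2 (methylglyoxal 10.1 to 20.4, others -13 to -2) and 78.4% in MDA-Pca-2b (22.3 to 24, others -12.3 to -10.5). Replicate 1 of C4-2 with methylglyoxal lay at 20.4, against 10.1 and 11.4 in its group. C4-2 replicate 3 at 7 mM glucose stood further from replicates 1 and 2 (11.2 and 9.37 times the counting variance) than these did from each other (2.82). Other groups gave 2.79 to 7.02.

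GLO1 codes for glyoxalase 1, the first enzyme that clears methylglyoxal, HAGH for the second, and PARK7 for a protein with reported deglycase activity. Neither 3 h of methylglyoxal nor 24 h of 25 mM glucose gave a change of GLO1 (ENSG00000124767, 6:38675925-38703145) beyond 0.15 on the log2 scale. In C4-2, GLO1 rose with methylglyoxal from 425 ± 35.4 to 473 ± 12.6 CPM (log2 0.15 ± 0.05, q = 0.0307, where q is the adjusted p of a gene). That call was lost without 7 mM replicate 1 (adjusted p = 0.208) or 2 (0.116), methylglyoxal replicate 1 (0.116) or 2 (0.0751). It was lost in a fit of 6 samples (0.0832) and against 25 mM glucose (log2 0.06, adjusted p = 0.5). In MDA-Pca-2b, GLO1 stood at 291 ± 7.12 CPM at 7 mM glucose and 290 ± 10.9 CPM with methylglyoxal (log2 -0.01 ± 0.05, q = 0.963). The difference between the lines was 0.16 ± 0.07 (q = 0.156; 0.0149 without C4-2 7 mM replicate 3). HAGH (ENSG00000063854, 16:1795620-1827157) gave -0.03 ± 0.06 in C4-2 (50.3 ± 2.28 to 49.2 ± 1.86 CPM, adjusted p = 0.774) and -0.02 ± 0.06 in MDA-Pca-2b (32.8 ± 0.341 to 32.4 ± 2.04 CPM, adjusted p = 0.87). HAGH overlaps FAHD1 on the other strand, so its counts may include reads of that gene. PARK7 (ENSG00000116288, 1:7954291-7985505) gave 0.09 ± 0.06 in C4-2 (399 ± 33.8 to 426 ± 37.7 CPM, adjusted p = 0.325) and 0.03 ± 0.07 in MDA-Pca-2b (316 ± 8.69 to 322 ± 24.1 CPM, adjusted p = 0.806). With 25 mM glucose GLO1 gave 0.09 ± 0.05 in C4-2 (452 ± 13.2 CPM, adjusted p = 0.419; 0.16 and 0.0425 without 7 mM replicate 3). It gave -0.11 ± 0.05 in MDA-Pca-2b (270 ± 4.9 CPM, adjusted p = 0.997), and the difference between the lines was 0.2 ± 0.07 (q = 0.261; 0.26 and 0.021 without C4-2 7 mM replicate 3). Of 18 genes on a list of methylglyoxal and aldehyde detoxification, 1 rose, 2 fell and 15 were not called with methylglyoxal in C4-2 (none adjusted over the list alone), with adjusted p = 0.993. In MDA-Pca-2b 2 fell and 16 were not called (adjusted p = 0.791).

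After 3 h of methylglyoxal, C4-2 cells carried more transcripts of the response to amino acid shortage (ATF4 targets), the only list that kept its call with an estimated correlation. With the preset correlation alone, immediate early genes, among others, were higher as a list, and S phase, mitosis and androgen lists were lower, with most members of these 3 not called. Genes of the chaperone response to heat did not move together. Of the 17503 genes, 1893 rose and 2140 fell (4033 called). The median absolute log2 change among called genes was 0.31, and 270 reached 1. The count fell to 2277 without methylglyoxal replicate 1 and to 2558 without 7 mM replicate 1. Against the 25 mM libraries 1666 genes were called, and 1386 of the 4033 kept their call.

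Of 33 ATF4 targets of the integrated stress response, 29 rose, 1 fell and 3 were not called in C4-2 (30 and 1 over the list alone). The list rose (adjusted p = 3.58e-94; adjusted p = 0.00028 with an estimated correlation). CHAC1 (ENSG00000128965, 15:40952962-40956512), a glutathione-degrading enzyme, rose from 4.49 ± 0.415 to 51 ± 16.6 CPM (log2 3.51 ± 0.17, q = 5.88e-14). The stress transcription factor genes DDIT3 (ENSG00000175197, 12:57516588-57521737; 9.44 ± 0.825 to 68.4 ± 30.7 CPM, log2 2.86 ± 0.19, q = 1.79e-11) and ATF3 (88.1 ± 19.4 to 377 ± 162 CPM, log2 2.1 ± 0.18, q = 2.98e-09) rose as well. DDIT3 overlaps the more abundant MARS1 on the other strand. The mTORC1 inhibitor SESN2 (17.6 ± 1.38 to 75.8 ± 19 CPM, log2 2.11 ± 0.11, q = 3.52e-13) and the cystine transporter SLC7A11 (63.2 ± 1.57 to 206 ± 19.4 CPM, log2 1.7 ± 0.07, q = 8.3e-16) rose in the same list. Methylglyoxal replicate 1 held the highest levels, with DDIT3 at 104, 51.8 and 49.5 CPM in replicates 1, 2 and 3. Among the largest rises of all genes were ASNSP1 (1.77 ± 0.0825 to 8.3 ± 1.5 CPM, log2 2.22 ± 0.17, q = 3.9e-10), a pseudogene of ASNS whose reads may come from that gene, and STYXL2 (1.49 ± 0.337 to 8.81 ± 2.06 CPM, log2 2.56 ± 0.2, q = 5.12e-10).

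**Figure D1:**
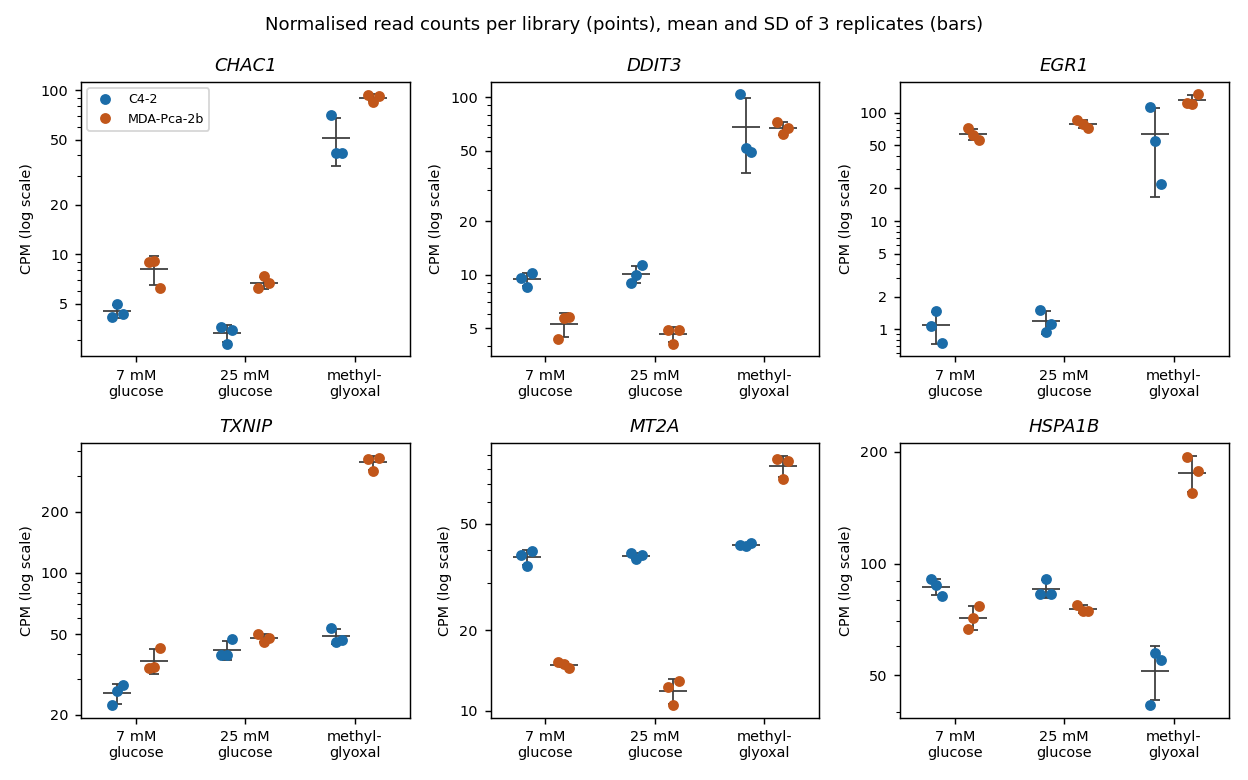
CPM of 6 stress and glucose-responsive genes in every library of both cell lines, by treatment. Points are libraries, bars give the mean and SD of 3 libraries, and the axis is logarithmic.

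Of 33 immediate early genes, 18 rose, 1 fell and 14 were not called in C4-2 (18 and 2 over the list alone). The list test gave adjusted p = 9.13e-11 upward (adjusted p = 0.185 with an estimated correlation). EGR1 (ENSG00000120738, 5:138465479-138469303) rose from 1.1 ± 0.361 to 63.5 ± 46.7 CPM (log2 5.84 ± 0.45, q = 4.25e-10), with 114, 54.6 and 21.9 CPM in replicates 1, 2 and 3. EGR2 (0.0378 ± 0.0375 to 2.47 ± 1.55 CPM, log2 5.81 ± 0.66, q = 4.42e-07) rose on 3 counts at 7 mM and 144 with methylglyoxal, a ratio of 63 (counting interval 21.1 to 309). EGR3 rose from 0.218 ± 0.0993 to 3.21 ± 2.41 CPM (log2 3.84 ± 0.52, q = 7.48e-06). In replicate 3 EGR2 stood at 0.701 and EGR3 at 0.607 CPM. KLF10, an early gene of transforming growth factor signals that is also on a list of MondoA and ChREBP targets, rose as well (36.4 ± 1.03 to 66.7 ± 16.8 CPM, log2 0.87 ± 0.1, q = 6.85e-07).

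Of 28 NRF2 targets 9 rose, 5 fell and 14 were not called in C4-2 (11 and 5 over the list alone). The list rose (adjusted p = 0.000578; adjusted p = 0.185 with an estimated correlation). HMOX1 went from 14.7 ± 1.78 to 29 ± 2.44 CPM (log2 0.98 ± 0.11, q = 3.08e-07) and TXNRD1 from 594 ± 24.3 to 824 ± 59.5 CPM (log2 0.47 ± 0.05, q = 1.33e-07). Of 24 unfolded protein response genes (ATF6 and XBP1 targets) 6 rose, 1 fell and 17 were not called (7 and 2 over the list alone; adjusted p = 0.00621 upward, adjusted p = 0.247 with an estimated correlation). HERPUD1 (79.9 ± 3.36 to 174 ± 26.9 CPM, log2 1.12 ± 0.07, q = 5.62e-12) and XBP1 (171 ± 8.83 to 310 ± 39 CPM, log2 0.86 ± 0.06, q = 2.2e-10) rose. Of 29 heat shock genes 5 rose, 2 fell and 22 were not called (adjusted p = 0.616). DNAJB4 rose from 23.8 ± 0.809 to 52.3 ± 14.6 CPM (log2 1.13 ± 0.12, q = 1.19e-07). HSPA1A (ENSG00000204389, 6:31815543-31817946; 2.85 ± 1.36 to 1.11 ± 0.336 CPM, log2 -1.34 ± 0.31, q = 0.00245) and HSPA1B (ENSG00000204388, 6:31827738-31830254; 86.7 ± 4.45 to 51.4 ± 8.52 CPM, log2 -0.75 ± 0.09, q = 7.18e-07) fell. These genes are nearly identical, and their sum gave -0.77 ± 0.09 (89.5 ± 4.98 to 52.5 ± 8.24 CPM, adjusted p = 7.3e-07). HSPA1A alone was not called against the 25 mM libraries (adjusted p = 0.0905). Of 31 proteasome genes 9 rose, 2 fell and 20 were not called (10 and 2 over the list alone; adjusted p = 0.00634 upward, adjusted p = 0.614 with an estimated correlation). The proteasome list was not called without 7 mM replicate 1 (adjusted p = 0.072) or against the 25 mM libraries (adjusted p = 0.481). PSMA3 rose from 179 ± 13.6 to 212 ± 12.5 CPM (log2 0.24 ± 0.06, q = 0.00519), which was lost without methylglyoxal replicate 1 (adjusted p = 0.0548) and against the 25 mM libraries (0.222).

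Of 24 p53 targets 5 rose and 19 were not called in C4-2 (7 rose over the list alone; adjusted p = 0.000847 upward, adjusted p = 0.144 with an estimated correlation). GDF15, a secreted stress factor known to respond to ATF4 too, rose from 30.4 ± 2.33 to 134 ± 29.5 CPM (log2 2.14 ± 0.13, q = 6.14e-12). PMAIP1, a pro-apoptotic BCL2 family gene, rose from 11.7 ± 0.134 to 35.4 ± 7.83 CPM (log2 1.6 ± 0.11, q = 2.51e-11), and GADD45A from 9.07 ± 0.911 to 16.3 ± 2.29 CPM (log2 0.85 ± 0.14, q = 5.75e-05). Of 10 glucose-sensing targets (genes driven by MondoA and ChREBP) 3 rose, 2 fell and 5 were not called (adjusted p = 0.0517). TXNIP (ENSG00000265972, 1:145992435-145996579) rose from 25.5 ± 2.92 to 48.7 ± 4.16 CPM (log2 0.94 ± 0.09, q = 6.84e-08) and ARRDC3 from 94.2 ± 6.48 to 125 ± 13.9 CPM (log2 0.41 ± 0.08, q = 0.000278). Neither was called against the 25 mM libraries (TXNIP log2 0.22, adjusted p = 0.137; ARRDC3 adjusted p = 0.055). Of 19 hypoxia genes 5 rose, 2 fell and 12 were not called (7 and 2 over the list alone; adjusted p = 0.0714). VEGFA rose from 54.5 ± 3.62 to 82.2 ± 9.29 CPM (log2 0.59 ± 0.07, q = 7.01e-07) and KDM3A from 36 ± 1.01 to 58.6 ± 5.89 CPM (log2 0.7 ± 0.07, q = 6.36e-08).

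Of 29 androgen-responsive genes 1 rose, 9 fell and 19 were not called in C4-2 (2 and 10 over the list alone; adjusted p = 0.00368 downward, adjusted p = 0.185 with an estimated correlation). PMEPA1 fell from 273 ± 7.22 to 202 ± 19.9 CPM (log2 -0.44 ± 0.06, q = 4.2e-06). KLK3, which codes for prostate-specific antigen, was not called (2320 ± 74.1 to 2480 ± 74.3 CPM, log2 0.1 ± 0.05, q = 0.146). Of 17 luminal cell markers 4 fell and 13 were not called (adjusted p = 0.00788 downward, adjusted p = 0.185 with an estimated correlation). HOXB13 fell from 276 ± 7.2 to 208 ± 8.1 CPM (log2 -0.41 ± 0.05, q = 7.88e-07). Of 24 S phase genes 10 fell and 14 were not called (13 fell over the list alone; adjusted p = 0.000578 downward, adjusted p = 0.307 with an estimated correlation). UHRF1 fell (80.5 ± 1.36 to 59.4 ± 4.59 CPM, log2 -0.44 ± 0.06, q = 3.67e-06). Of 22 G2 and mitosis genes 1 rose, 7 fell and 14 were not called (1 and 8 over the list alone; adjusted p = 0.00621 downward, adjusted p = 0.307 with an estimated correlation). CCNF (51.1 ± 6.5 to 30.9 ± 2.79 CPM, log2 -0.73 ± 0.08, q = 4.08e-07), PLK1 (136 ± 12.8 to 93.5 ± 7.29 CPM, log2 -0.54 ± 0.06, q = 7.88e-07) and MKI67 (396 ± 42.7 to 312 ± 34.6 CPM, log2 -0.34 ± 0.07, q = 0.000709) fell.

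Of 24 glycolysis genes 2 rose, 8 fell and 14 were not called in C4-2 (2 and 9 over the list alone; adjusted p = 0.0554), with PFKL lower (107 ± 3.85 to 86.2 ± 0.929 CPM, log2 -0.32 ± 0.06, q = 0.000147). Of 24 cholesterol synthesis genes 4 rose, 5 fell and 15 were not called (5 and 6 over the list alone; adjusted p = 0.771), with LSS lower (91.3 ± 5.64 to 68.9 ± 4.04 CPM, log2 -0.41 ± 0.06, q = 1.07e-05). Of 14 fatty acid synthesis genes 2 rose, 5 fell and 7 were not called (2 and 6 over the list alone; adjusted p = 0.0793). FASN fell from 1020 ± 199 to 661 ± 77.8 CPM (log2 -0.63 ± 0.1, q = 4.98e-05). SREBF1, which overlaps RAI1 on the other strand, fell from 266 ± 26.1 to 199 ± 17.4 CPM (log2 -0.42 ± 0.08, q = 0.000194; 0.303 against the 25 mM libraries). Of 13 mitochondrially encoded transcripts 9 rose and 4 were not called (10 rose over the list alone; adjusted p = 0.00209 upward, adjusted p = 0.402 with an estimated correlation). MT-CO2 rose from 5260 ± 412 to 6690 ± 279 CPM (log2 0.35 ± 0.08, q = 0.00197; 0.965 against the 25 mM libraries). The mitochondrial list turned downward against the 25 mM libraries without a call (adjusted p = 0.384). Of 65 ribosomal protein genes 26 rose and 39 were not called (46 rose over the list alone; adjusted p = 1.51e-08 upward, adjusted p = 0.494 with an estimated correlation). RPL39, which has near-identical pseudogenes, rose (384 ± 21.9 to 522 ± 90 CPM, log2 0.44 ± 0.09, q = 0.000515).

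Of 8 receptors of glycated protein 2 fell and 6 were not called in C4-2 (adjusted p = 0.0703), with SCARB1 lower (126 ± 13.7 to 94.2 ± 3.66 CPM, log2 -0.42 ± 0.06, q = 1.14e-05). Of 15 NF-kB targets 2 rose, 1 fell and 12 were not called (adjusted p = 0.87), and of 18 interferon genes 2 fell and 16 were not called (0.771). Of 10 epithelial-mesenchymal genes 3 rose, 1 fell and 6 were not called (adjusted p = 0.842). No member was called of 6 metallothioneins (adjusted p = 0.771), 6 basal markers (0.808), 3 neuroendocrine markers (0.866), 5 fibroblast markers (0.993) or 2 leukocyte markers (0.816). The median, mean and test differed in sign for detoxification, NF-kB, metallothionein, epithelial-mesenchymal and fibroblast lists, none of them called. The largest falls of all genes by the naming rule were TUBA1A (9.58 ± 3.09 to 4.52 ± 0.421 CPM, log2 -1.08 ± 0.24, q = 0.00141), INAVA (7.75 ± 1.87 to 4.16 ± 0.0327 CPM, log2 -0.89 ± 0.14, q = 4.69e-05), SGPP2 (7.25 ± 1.32 to 3.91 ± 0.746 CPM, log2 -0.88 ± 0.14, q = 6.43e-05), EIF4A1 (11.3 ± 3.14 to 6.31 ± 1.76 CPM, log2 -0.85 ± 0.19, q = 0.00212) and WDR81 (37.8 ± 5.43 to 21.3 ± 1.49 CPM, log2 -0.83 ± 0.1, q = 7.37e-07). TUBA1A overlaps TUBA1C, WDR81 overlaps MIR22HG, and EIF4A1 shares its exons with a readthrough gene. TUBA1A (adjusted p = 0.0623), SGPP2 (0.19) and EIF4A1 (0.13) were not called against the 25 mM libraries.

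In MDA-Pca-2b cells 3 h of methylglyoxal was followed by higher transcripts of the same amino acid response and of metallothioneins, glucose-sensing genes and p53 targets. With the preset correlation alone, the heat shock list, among others, was higher and the S phase and fatty acid synthesis lists were lower. Of the 17503 genes, 2949 rose and 3172 fell (6121 called). The median absolute log2 change among called genes was 0.41, and 769 reached 1. Against the 25 mM libraries 5279 of the 6121 kept their call.

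Of 33 ATF4 targets 28 rose, 1 fell and 4 were not called in MDA-Pca-2b (adjusted p = 1.15e-38 upward; adjusted p = 0.00418 with an estimated correlation). ATF3 (28.1 ± 2.5 to 398 ± 25.5 CPM, log2 3.83 ± 0.2, q = 2.81e-14), DDIT3 (5.29 ± 0.808 to 67.1 ± 5.47 CPM, log2 3.65 ± 0.21, q = 1.44e-13) and CHAC1 (8.11 ± 1.6 to 90.2 ± 4.23 CPM, log2 3.48 ± 0.15, q = 1.31e-15) rose. All 6 metallothioneins rose (adjusted p = 2.34e-35; adjusted p = 1.84e-05 with an estimated correlation). MT1E went from 0.771 ± 0.433 to 9.99 ± 1.07 CPM (log2 3.73 ± 0.26, q = 2.27e-11), MT1G from 0.984 ± 0.0437 to 11.9 ± 1.57 CPM (log2 3.59 ± 0.21, q = 1.94e-13) and MT1F from 0.745 ± 0.0759 to 4.45 ± 0.664 CPM (log2 2.57 ± 0.22, q = 4.58e-10). The sum of these similar genes rose from 21.3 ± 1.26 to 126 ± 10.7 CPM (log2 2.57 ± 0.08, q = 3.55e-19). The largest rises by the naming rule included ROCK1P1 (2.82 ± 0.347 to 33.4 ± 1.87 CPM, log2 3.56 ± 0.15, q = 7.9e-16), a partial copy of ROCK1. The largest falls were EIF4A1 (17.2 ± 1.57 to 6.26 ± 1.43 CPM, log2 -1.46 ± 0.18, q = 4.44e-07), GAS6-AS1 (5.89 ± 0.0814 to 2.14 ± 0.543 CPM, log2 -1.46 ± 0.18, q = 2.36e-07), SULT1A1 (9.15 ± 0.529 to 3.35 ± 0.784 CPM, log2 -1.45 ± 0.16, q = 6.25e-08), HPN-AS1 (7.45 ± 0.843 to 2.76 ± 0.199 CPM, log2 -1.43 ± 0.2, q = 2.01e-06) and ACP4 (7.82 ± 1.38 to 2.95 ± 0.548 CPM, log2 -1.41 ± 0.21, q = 5.05e-06). GAS6-AS1 and HPN-AS1 overlap GAS6 and HPN, ACP4 overlaps 2 antisense genes, and SULT1A1 has near-identical copies.

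Of 28 NRF2 targets 10 rose, 4 fell and 14 were not called in MDA-Pca-2b (adjusted p = 0.00188 upward; adjusted p = 0.232 with an estimated correlation). HMOX1 (3.77 ± 0.858 to 14.2 ± 0.805 CPM, log2 1.92 ± 0.14, q = 1.25e-11), SLC7A11 (143 ± 7.14 to 346 ± 28.8 CPM, log2 1.28 ± 0.06, q = 9.86e-15) and MAFG (34.5 ± 0.362 to 63.6 ± 2.88 CPM, log2 0.88 ± 0.07, q = 2.97e-11), which overlaps SIRT7, rose. Of 29 heat shock genes 15 rose, 1 fell and 13 were not called (adjusted p = 9.56e-11 upward; adjusted p = 0.137 with an estimated correlation). RGS2, a regulator of G protein signalling on that list, rose from 16.5 ± 1.09 to 149 ± 4.13 CPM (log2 3.18 ± 0.09, q = 1.12e-19). DNAJB4 (9.57 ± 0.799 to 60.2 ± 3.01 CPM, log2 2.65 ± 0.13, q = 9.82e-15), HSPA6 (0.626 ± 0.0695 to 3.7 ± 1.06 CPM, log2 2.56 ± 0.28, q = 3.71e-08) and HSPA1A (120 ± 3.33 to 261 ± 38.8 CPM, log2 1.12 ± 0.1, q = 9.85e-10) rose. The sum of HSPA1A and HSPA1B gave 1.19 ± 0.08 (191 ± 5.7 to 436 ± 58 CPM, adjusted p = 8.68e-12). Of 24 ATF6 and XBP1 targets 4 rose, 12 fell and 8 were not called (4 and 14 over the list alone; adjusted p = 0.318). HERPUD1 (123 ± 2.47 to 254 ± 6.56 CPM, log2 1.04 ± 0.07, q = 1.5e-12), ERN1 (18.4 ± 1.84 to 37.6 ± 2.96 CPM, log2 1.03 ± 0.08, q = 1.67e-10) and XBP1 (190 ± 3.43 to 353 ± 12.2 CPM, log2 0.9 ± 0.06, q = 1.25e-11) were among those that rose. Of 33 immediate early genes 18 rose, 4 fell and 11 were not called (19 and 5 over the list alone; adjusted p = 1.85e-06 upward, adjusted p = 0.236 with an estimated correlation). DUSP8 (11.8 ± 0.572 to 48.7 ± 4.5 CPM, log2 2.05 ± 0.11, q = 2.17e-14) and JUN (70.5 ± 19.5 to 286 ± 21 CPM, log2 2.02 ± 0.13, q = 3.34e-12) rose. Of 31 proteasome genes 8 rose and 23 were not called (7 rose over the list alone; adjusted p = 0.26).

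Of 24 p53 targets 12 rose and 12 were not called in MDA-Pca-2b (13 rose and 1 fell over the list alone; adjusted p = 5.73e-06 upward, adjusted p = 0.0137 with an estimated correlation). BBC3 (2.66 ± 0.966 to 12.5 ± 0.384 CPM, log2 2.23 ± 0.2, q = 7.28e-10), PMAIP1 (24.1 ± 1.89 to 82.6 ± 0.789 CPM, log2 1.78 ± 0.1, q = 7.26e-14) and GDF15 (220 ± 49 to 665 ± 45.7 CPM, log2 1.6 ± 0.12, q = 2.21e-11) rose. Of 10 glucose-sensing targets 5 rose, 3 fell and 2 were not called (adjusted p = 2.67e-08 upward; adjusted p = 0.00289 with an estimated correlation). TXNIP, an inhibitor of glucose uptake, rose from 37 ± 5.13 to 350 ± 27.3 CPM (log2 3.24 ± 0.09, q = 1.12e-19). Its relatives ARRDC3 (24.5 ± 1.65 to 119 ± 10.6 CPM, log2 2.28 ± 0.08, q = 6.08e-17) and ARRDC4 (10.7 ± 0.335 to 25.7 ± 0.41 CPM, log2 1.27 ± 0.08, q = 2.12e-12) rose as well. Of 24 glycolysis genes 9 fell and 15 were not called (adjusted p = 0.0347 downward; adjusted p = 0.429 with an estimated correlation). HK2 (205 ± 3.06 to 153 ± 4.8 CPM, log2 -0.42 ± 0.05, q = 2.93e-08) and the lactate transporter SLC16A1 (146 ± 2.47 to 113 ± 3.85 CPM, log2 -0.37 ± 0.05, q = 1.07e-06) fell. The glycolysis list was not called without methylglyoxal replicate 2 (adjusted p = 0.102). Of 19 hypoxia genes 3 rose, 4 fell and 12 were not called (3 and 5 over the list alone; adjusted p = 0.935). ADM (2.79 ± 0.291 to 7.95 ± 0.715 CPM, log2 1.5 ± 0.19, q = 2.7e-07) and VEGFA (128 ± 3.9 to 249 ± 9.87 CPM, log2 0.96 ± 0.06, q = 4.74e-12) rose.

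Of 29 androgen-responsive genes 5 rose, 11 fell and 13 were not called in MDA-Pca-2b (adjusted p = 0.935). ZBTB10 (72.8 ± 5.08 to 227 ± 11.1 CPM, log2 1.64 ± 0.06, q = 1.5e-16) and C1orf116 (166 ± 3.56 to 248 ± 14 CPM, log2 0.58 ± 0.05, q = 8.41e-11) rose. KLK3 fell from 4110 ± 46.2 to 3780 ± 189 CPM (log2 -0.12 ± 0.05, q = 0.0447). That call was lost without 7 mM replicate 1 (adjusted p = 0.111), 2 (0.0949) or 3 (0.0725), and without methylglyoxal replicate 2 (0.202) or 3 (0.106), and against the 25 mM libraries (0.195), with no filter (0.138) and in fits of 9 (0.0797) or 6 samples (0.117). Of 17 luminal markers 2 rose, 5 fell and 10 were not called (adjusted p = 0.318). FOXA1, which overlaps TTC6, rose from 444 ± 14.3 to 617 ± 27.6 CPM (log2 0.47 ± 0.04, q = 2.01e-09). Of 24 cholesterol synthesis genes 5 rose, 6 fell and 13 were not called (adjusted p = 0.935), with LSS lower (113 ± 3.76 to 72.3 ± 2.35 CPM, log2 -0.65 ± 0.06, q = 7.06e-10). Of 14 fatty acid synthesis genes 1 rose, 9 fell and 4 were not called (adjusted p = 0.0135 downward; adjusted p = 0.255 with an estimated correlation). FASN (2510 ± 343 to 1700 ± 58.4 CPM, log2 -0.57 ± 0.1, q = 4.09e-05) and ELOVL6 (76.1 ± 9.21 to 52.6 ± 0.83 CPM, log2 -0.53 ± 0.07, q = 4.6e-07) fell.

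Of 24 S phase genes 21 fell and 3 were not called in MDA-Pca-2b (22 fell over the list alone; adjusted p = 9.56e-11 downward, adjusted p = 0.0578 with an estimated correlation). GINS1 (85.6 ± 5.12 to 54.5 ± 3.14 CPM, log2 -0.65 ± 0.06, q = 1.05e-09), UHRF1 (103 ± 1.23 to 69.2 ± 3.79 CPM, log2 -0.57 ± 0.06, q = 4.55e-09) and CLSPN (70.5 ± 5.68 to 47.4 ± 2.94 CPM, log2 -0.57 ± 0.06, q = 3.17e-08) fell. Of 22 G2 and mitosis genes 3 rose, 6 fell and 13 were not called (4 and 7 over the list alone; adjusted p = 0.318). CCNA2, which overlaps EXOSC9 (119 ± 7.19 to 84 ± 1.04 CPM, log2 -0.51 ± 0.06, q = 1.72e-07), and MKI67 (730 ± 37.8 to 524 ± 24.8 CPM, log2 -0.48 ± 0.07, q = 3.11e-06) fell. Of 8 receptors of glycated protein 2 fell and 6 were not called (adjusted p = 0.558). Of 15 NF-kB targets 4 rose, 2 fell and 9 were not called (adjusted p = 0.98). Of 10 epithelial-mesenchymal genes 1 rose, 4 fell and 5 were not called (adjusted p = 0.218). ITGA5 was higher (13.3 ± 0.0954 to 31.8 ± 2.06 CPM, log2 1.26 ± 0.11, q = 5.47e-10) and TWIST1 lower (32.3 ± 1.03 to 16.9 ± 0.709 CPM, log2 -0.93 ± 0.11, q = 8.44e-08). Of 18 interferon genes 2 rose, 4 fell and 12 were not called (adjusted p = 0.558). Of 65 ribosomal protein genes 1 fell and 64 were not called (none over the list alone; adjusted p = 0.754). Of 6 basal markers 2 fell and 4 were not called (adjusted p = 0.558), and of 5 fibroblast markers 1 fell and 4 were not called (0.754). No member was called of 13 mitochondrially encoded transcripts (adjusted p = 0.936), 3 neuroendocrine markers (0.935) or 2 leukocyte markers (0.935). The median, mean and test differed in sign for the detoxification, receptor, NF-kB, hypoxia, androgen, cholesterol, interferon and neuroendocrine lists, none of them called.

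The methylglyoxal effects of the lines differed in the metallothionein and glucose-sensing lists with either correlation setting. Heat shock, S phase, unfolded protein response and 3 further lists differed with the preset correlation alone. In 1088 genes the change was higher in C4-2 and in 1473 it was lower (2561 called of 17503; 248 by at least 1). Whether that balance depends on the length and GC trend varied with how the trend was removed. In genes over 8 CPM 1112 were higher and 1487 lower, against 1514 and 1428 with the trend removed. Removal in all genes left 1117 higher and 1549 lower, or 1457 and 1459 by the trend of genes over 8 CPM. Dose and time were the same, but the media differ, so the difference is one of line and medium together. Against the 25 mM libraries 2090 genes were called, and 1369 of the 2561 kept their call.

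Of 6 metallothioneins 5 had a lower change in C4-2 and 1 was not called (adjusted p = 4.26e-31; adjusted p = 2.44e-05 with an estimated correlation). MT2A (ENSG00000125148, 16:56608584-56609497) gave 0.15 ± 0.07 in C4-2 (37.4 ± 2.37 to 41.6 ± 0.581 CPM) and 2.46 ± 0.08 in MDA-Pca-2b (difference -2.31 ± 0.1, q = 2.81e-14). MT1F differed by -2.5 ± 0.31 (q = 2.35e-06), and MT1G by -6.02 ± 0.97 (q = 8.15e-05) on 9 and 1 counts in C4-2. Of 29 heat shock genes 1 had a higher and 10 a lower change in C4-2, and 18 were not called (1 and 12 over the list alone; adjusted p = 1.17e-13, adjusted p = 0.139 with an estimated correlation). RGS2 differed by -2.58 ± 0.12 (q = 2.81e-14) and HSPA1A by -2.46 ± 0.32 (q = 4.92e-06), and the sum of HSPA1A and HSPA1B by -1.96 ± 0.12 (q = 1.08e-11). Of 10 glucose-sensing targets 3 had a lower change in C4-2 and 7 were not called (adjusted p = 6.81e-08; adjusted p = 0.00253 with an estimated correlation). TXNIP differed by -2.3 ± 0.13 (q = 1.41e-12), ARRDC3 by -1.87 ± 0.11 (6.25e-12) and ARRDC4 by -1.14 ± 0.11 (9.11e-08).

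**Figure D2:**
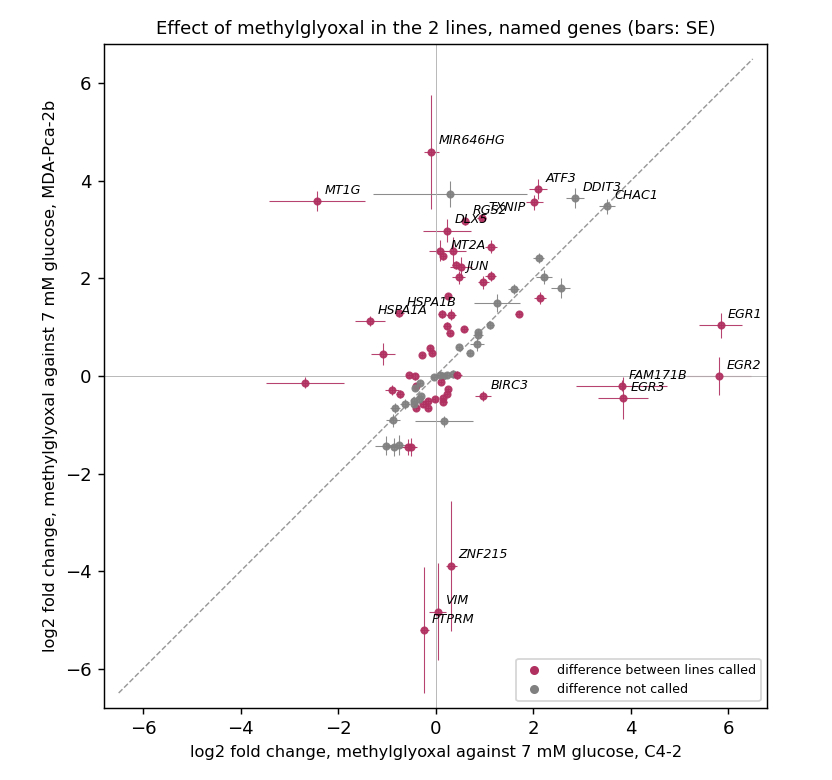
Log2 fold change with methylglyoxal in C4-2 (horizontal) against MDA-Pca-2b (vertical) for the named genes, with SE bars. Red points are genes whose change differs between the lines by the test, grey points are not called, and the dashed line marks equal change.

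Immediate early genes differed in both directions, with 8 higher, 9 lower and 16 not called of 33 (9 and 9 over the list alone; adjusted p = 0.928). EGR1 (difference 4.8 ± 0.56, q = 1.02e-06), EGR2 (5.82 ± 0.82, q = 1.67e-05) and EGR3 (4.3 ± 0.69, q = 8.58e-05) had a higher change in C4-2. Of 33 ATF4 targets 6 were higher, 3 lower and 24 not called (6 and 4 over the list alone; adjusted p = 0.768), with ATF3 lower (-1.73 ± 0.26, q = 3.24e-05). Of 28 NRF2 targets 4 were higher, 5 lower and 19 not called (4 and 7 over the list alone; adjusted p = 0.591), with HMOX1 lower (-0.93 ± 0.18, q = 0.000467) and SLC7A11 higher (0.43 ± 0.09, q = 0.00149). Of 24 ATF6 and XBP1 targets 8 were higher, 1 lower and 15 not called (10 and 1 over the list alone; adjusted p = 0.000121 upward, adjusted p = 0.142 with an estimated correlation). HSP90B1 (0.52 ± 0.07, q = 1.77e-05) and SEL1L (0.6 ± 0.07, q = 1.9e-06) were among them. Of 24 p53 targets 3 were higher, 8 lower and 13 not called (4 and 9 over the list alone; adjusted p = 0.0332 downward, adjusted p = 0.247 with an estimated correlation), with BBC3 lower (-1.71 ± 0.29, q = 0.000175). The p53 list was lost without C4-2 7 mM replicate 3 (adjusted p = 0.103), MDA-Pca-2b 7 mM replicate 1 (0.0748), C4-2 methylglyoxal replicate 2 (0.0521) or 3 (0.0851).

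Of 24 S phase genes 13 had a higher change in C4-2 and 11 were not called (14 over the list alone; adjusted p = 5.31e-07, adjusted p = 0.189 with an estimated correlation). GINS1 (0.5 ± 0.08, q = 8.72e-05) and PCNA (0.47 ± 0.08, q = 0.00011) were 2 of these. Of 65 ribosomal protein genes 2 were higher and 63 not called (1 over the list alone; adjusted p = 0.00013 upward, adjusted p = 0.946 with an estimated correlation). Of 13 mitochondrially encoded transcripts 1 was higher and 12 not called (4 over the list alone; adjusted p = 0.0262 upward, adjusted p = 0.81 with an estimated correlation). The mitochondrial list was not called without C4-2 7 mM replicate 2 (adjusted p = 0.0798), MDA-Pca-2b 7 mM replicate 1 (0.14), C4-2 methylglyoxal replicate 1 (0.0801) or MDA-Pca-2b methylglyoxal replicate 1 (0.159). Against the 25 mM libraries the ribosomal (adjusted p = 0.453) and mitochondrial (0.608) lists turned downward without a call. Of 29 androgen-responsive genes 1 was higher, 6 lower and 22 not called (1 and 7 over the list alone; adjusted p = 0.0968), with ZBTB10 (-1.37 ± 0.09, q = 1.53e-11) and TMPRSS2 (-0.71 ± 0.07, q = 2.13e-08) lower. Of 17 luminal markers 1 was higher, 2 lower and 14 not called (adjusted p = 0.763), with FOXA1 lower (-0.55 ± 0.06, q = 8.39e-07). Of 24 glycolysis genes 3 were higher, 1 lower and 20 not called (adjusted p = 0.538), with SLC16A1 higher (0.6 ± 0.07, q = 9.76e-07). Of 15 NF-kB targets 2 were higher, 2 lower and 11 not called (adjusted p = 0.768), with BIRC3 higher (1.38 ± 0.19, q = 1.27e-05).

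The remaining lists gave no call for this difference. Higher, lower and not called were 3, 2 and 14 for hypoxia (4 and 2 over the list alone; adjusted p = 0.149), 1, 3 and 20 for cholesterol synthesis (0.768) and 4, 1 and 9 for fatty acid synthesis (6 and 1 over the list alone; 0.128). They were 3, 5 and 14 for G2 and mitosis (4 and 6 over the list alone; 0.763), 2, 1 and 7 for the epithelial-mesenchymal transition (0.431) and 1, 1 and 16 for interferon (1 higher over the list alone; 0.928). Of 31 proteasome genes 1 was lower and 30 not called (none over the list alone; adjusted p = 0.768), and of 8 receptors of glycated protein 1 was lower and 7 not called (0.768). No member was called of the detoxification list (0.763), basal markers (0.928), neuroendocrine markers (0.928), fibroblast markers (0.768) or leukocyte markers (0.768). The median, mean and test differed in sign for the ATF4, androgen, fatty acid, interferon and neuroendocrine lists. Among the largest differences by the naming rule, VIM (4.87 ± 1.02, q = 0.00149), PTPRM (4.97 ± 1.31, q = 0.0111; 0.0579 without MDA-Pca-2b 7 mM replicate 2) and ZNF215 (4.21 ± 1.34, q = 0.035) are C4-2 transcripts that stood at 0.965 CPM or less in MDA-Pca-2b at 7 mM. The ZNF215 call was lost without MDA-Pca-2b 7 mM replicate 1 (adjusted p = 0.0888) or 2 (0.152) and without MDA-Pca-2b methylglyoxal replicate 1 (0.0778), 2 (0.0755) or 3 (0.0804). FAM171B (4.01 ± 0.93, q = 0.00362) and TMEM150C (-2.53 ± 0.82, q = 0.0361) stood at a mean of 0.259 CPM or less in C4-2. TMEM150C was lost without C4-2 7 mM replicate 1 (adjusted p = 0.104) or 2 (0.13), MDA-Pca-2b 7 mM replicate 3 (0.0505), or C4-2 methylglyoxal replicate 1 (0.0628), 2 (0.0594) or 3 (0.155), by DESeq2 (0.0574) and with the block (0.0516). DLX5 differed by -2.74 ± 0.57 (q = 0.00126) and MIR646HG by -4.69 ± 1.18 (q = 0.00762), the latter on 9 and 0 counts in MDA-Pca-2b. Against the 25 mM libraries VIM (2.78, adjusted p = 0.234), PTPRM (3.86, 0.105), ZNF215 (2.76, 0.284), FAM171B (2.1, 0.0655), DLX5 (-1.57, 0.164) and MT1G (-4.77, 0.0551) were not called.

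The lines shared much of the methylglyoxal response. In both, 1157 genes rose (319 expected if the calls were independent) and 1089 fell (388 expected). Of 2387 genes called in both, 94.1% went the same way, 55 rose in C4-2 and fell in MDA-Pca-2b, and 86 did the reverse. Log2 fold changes correlated at 0.31 (Spearman 0.39), and in 9633 genes over 8 CPM at 0.61 (0.55). Within a line, methylglyoxal and 25 mM glucose share the 7 mM libraries, which alone makes their changes go together. In C4-2 TXNIP was the 1 gene raised by both treatments (0.324 expected; 3 genes by RLE, 281 by DESeq2). Fold changes correlated at 0.56 (Spearman 0.67; 0.46 to 0.51 in 10 simulations of unchanged groups). In MDA-Pca-2b 2 genes, UGT2B11 and UGT2B28, fell with both (0.362 expected), but the 7 similar UGT2B genes summed rose with methylglyoxal (190 ± 3.41 to 241 ± 1.74 CPM, log2 0.34 ± 0.06, adjusted p = 3.16e-05). The correlation was 0.03 (simulated 0.47 to 0.52).

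Raising glucose from 7 to 25 mM for 24 h left few transcripts called in C4-2. TXNIP, a glucose-responsive gene, rose from 25.5 ± 2.92 to 41.8 ± 4.54 CPM (log2 0.71 ± 0.09, q = 0.00091). By edgeR 3 genes rose and 17500 were not called. Unadjusted, 2691 genes had p under 0.05, against 875 expected by chance. DESeq2 called 460 (343 higher) but kept 1 of the 3, and the unfiltered table gave 354 (142 higher). The count was 1447 (549 higher) without 7 mM replicate 3, 5 without 25 mM replicate 2, 2 without 25 mM replicate 1 or 7 mM replicate 2, and 1 without 7 mM replicate 1. The other 2 genes were the cancer-testis antigen genes GAGE12G (ENSG00000215269, X:49570400-49577754; 0.14 ± 0.0412 to 8.06 ± 6.94 CPM, log2 5.8 ± 0.87, q = 0.0148) and GAGE13 (1.01 ± 0.403 to 5.49 ± 2.93 CPM, log2 2.44 ± 0.37, q = 0.0148). GAGE12G held 235, 298 and 5 counts in the 25 mM replicates, where its near-identical relative GAGE2A held 602, 553 and 157. The 11 GAGE genes summed gave 28 ± 1 CPM at 7 mM and 34 ± 14.7 CPM at 25 mM (log2 0.28 ± 0.18, q = 0.468). GAGE12G was lost without 7 mM replicate 1 (adjusted p = 0.221), 7 mM replicate 2 (0.149) or 25 mM replicate 1 (0.0617), and GAGE13 without 7 mM replicate 1 (0.221), 25 mM replicate 1 (0.0752) or 25 mM replicate 3 (0.0771).

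By list, 1 of 10 glucose-sensing targets rose in C4-2 at 25 mM glucose and 9 were not called (2 rose over the list alone), with adjusted p = 0.041 upward (adjusted p = 0.491 with an estimated correlation). That list was not called without 7 mM replicate 3 (adjusted p = 0.112), 25 mM replicate 1 (0.0575) or 25 mM replicate 3 (0.147). No member of any other list was called over all genes. Of 13 mitochondrially encoded transcripts 9 rose over the list alone, and the list rose (adjusted p = 4.32e-13; adjusted p = 0.348 with an estimated correlation). Ribosomal proteins (adjusted p = 1.66e-05), proteasome (0.000129) and heat shock genes (0.00545) were higher as lists and immediate early genes lower (0.00545). None of these was called with the estimated correlation (adjusted p = 0.64 for ribosomal proteins, 0.636 for the others). Ribosomal proteins were lost without 7 mM replicate 2 (adjusted p = 0.0625) or 25 mM replicate 1 (0.115), and without 7 mM replicate 1 heat shock (0.0616) and immediate early genes (0.0931) were lost. Over the list alone, cholesterol synthesis had 5 of 24 higher (adjusted p = 0.0608), G2 and mitosis 4 higher and 2 lower of 22 (0.0631), fatty acid synthesis 3 of 14 lower (0.314), receptors of glycated protein 2 of 8 lower (0.0631) and luminal markers 2 higher and 1 lower of 17 (0.611). Lists with 1 such gene in a direction were ATF4 (1 higher, 1 lower; adjusted p = 0.213), NRF2 (1 lower; 0.773), unfolded protein response (1 higher; 0.334), p53 (1 higher; 0.187), glycolysis (1 lower; 0.845), S phase (1 higher; 0.153), heat shock (1 higher) and leukocyte markers (1 higher; 0.769). None were called either way in detoxification (0.422), NF-kB (0.428), hypoxia (0.611), androgen (0.0843), metallothioneins (0.526), epithelial-mesenchymal (0.334), interferon (0.428), basal (0.712), neuroendocrine (0.422) and fibroblast (0.228) lists. Median, mean and test differed in sign for receptors, NRF2, glycolysis and cholesterol synthesis.

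In MDA-Pca-2b 4 of 17503 genes were called at 25 mM glucose. CYP11A1 (ENSG00000140459, 15:74337759-74367646), whose product makes pregnenolone from cholesterol, rose from 2.94 ± 0.224 to 6.52 ± 0.99 CPM (log2 1.15 ± 0.17, q = 0.00196). DRAM1, an autophagy gene, rose from 12.2 ± 0.576 to 17.3 ± 1.83 CPM (log2 0.5 ± 0.08, q = 0.0137). UGT2B11 (51 ± 1.01 to 36.2 ± 2.73 CPM, log2 -0.49 ± 0.07, q = 0.00196) and UGT2B28 (12.5 ± 1.28 to 7.99 ± 0.773 CPM, log2 -0.65 ± 0.11, q = 0.0218) fell. The 7 similar UGT2B genes summed gave -0.27 ± 0.06 (158 ± 7.88 CPM at 25 mM, adjusted p = 0.443). DRAM1 was lost without 7 mM replicate 2 (adjusted p = 0.14) or 25 mM replicate 1 (0.199) and in fits of 9 (0.214) or 6 samples (0.203). UGT2B28 was lost without 7 mM replicate 2 (adjusted p = 0.333) or 3 (0.0702), 25 mM replicate 1 (0.175) or 2 (0.361) and in those fits (0.0677 and 0.149). The count was 2 without 7 mM replicate 2, and 820 genes had unadjusted p under 0.05 (875 expected by chance). TXNIP was not called (37 ± 5.13 to 47.9 ± 2.11 CPM, log2 0.37 ± 0.09, q = 0.523), although the unfiltered table, where 22 genes were called, gave adjusted p = 6.68e-05.

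No list member was called over all genes in MDA-Pca-2b at 25 mM glucose, but 6 lists were. Ribosomal proteins (adjusted p = 5.64e-18), ATF4 targets (0.000114), detoxification genes (0.036) and the proteasome (0.036) were lower, and immediate early genes (3.6e-05) and glucose-sensing targets (0.00458; 2 of 10 higher over the list alone) were higher. None was called with the estimated correlation (adjusted p = 0.251 for glucose-sensing, 0.924 for the proteasome and 0.552 for each of the others). The glucose-sensing list was lost without 7 mM replicate 2 (adjusted p = 0.0506). The detoxification list was lost without 7 mM replicate 2 (0.0966) or 3 (0.118) and without 25 mM replicate 1 (0.0897) or 2 (0.166). The proteasome list was lost without 7 mM replicate 1 (0.195) or 2 (0.0759) and without 25 mM replicate 2 (0.409). Over the list alone, 1 member was lower in the detoxification, metallothionein (adjusted p = 0.136) and epithelial-mesenchymal (0.225) lists. Lists with none called either way were receptors (0.915), NRF2 (0.531), heat shock (0.357), unfolded protein response (0.357), NF-kB (0.798), p53 (0.872), glycolysis (0.907), hypoxia (0.687), androgen (0.915), cholesterol (0.872), fatty acid (0.357), S phase (0.357), G2 and mitosis (0.857), interferon (0.798), mitochondrial (0.93), luminal (0.357), basal (0.907), neuroendocrine (0.884), fibroblast (0.857) and leukocyte (0.872). The median, mean and test differed in sign for p53, glycolysis, interferon, mitochondrial, basal and neuroendocrine lists.

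For the difference of the glucose effects between the lines, edgeR called 0 of 17503 genes, with 2450 at unadjusted p under 0.05. DESeq2 called 210 (174 higher in C4-2), and the unfiltered table gave 164 (80 higher). Without C4-2 7 mM replicate 3 the count was 905 (390 higher), and without C4-2 25 mM replicate 2 it was 1. TXNIP differed by 0.35 ± 0.13 (q = 0.27; 0.0361 in the unfiltered table). Ribosomal proteins (adjusted p = 3.84e-16), mitochondrially encoded transcripts (1.66e-07; 6 of 13 higher over the list alone), proteasome (1.98e-05) and heat shock (0.0111) lists had a higher change in C4-2, and immediate early genes a lower one (6.83e-06). All 5 were lost with the estimated correlation (adjusted p = 0.854 for each). The heat shock list was lost without C4-2 7 mM replicate 1 (adjusted p = 0.0629), MDA-Pca-2b 7 mM replicate 2 (0.0514) or MDA-Pca-2b 25 mM replicate 3 (0.0521). Over the list alone, higher and lower genes were 4 and 1 for cholesterol (adjusted p = 0.358), 1 and 1 for fatty acid (0.262), 1 and 2 for receptors (0.349), 2 higher for S phase (0.0952), 3 lower for G2 and mitosis (0.383) and 1 lower for glycolysis (0.957). They were 1 higher each for ATF4 (0.576), metallothioneins (0.97), epithelial-mesenchymal (0.957) and leukocyte (0.957) lists. None were called in detoxification (0.0708), NRF2 (0.957), unfolded protein response (0.97), NF-kB (0.97), p53 (0.597), glucose-sensing (0.97), hypoxia (0.611), androgen (0.307), interferon (0.957), luminal (0.957), basal (0.919), neuroendocrine (0.827) and fibroblast (0.919) lists. The median, mean and test differed in sign for glycolysis, glucose-sensing, cholesterol, metallothionein, epithelial-mesenchymal and luminal lists.

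At 7 mM glucose the lines differed in most genes, with 6725 higher and 6374 lower in C4-2 (13099 called, 74.8%; 6028 by a log2 of at least 1). Line and medium cannot be told apart here, and the levels not repeated below are those given above. C4-2 held more GLO1 (log2 0.55 ± 0.05, q = 2.83e-10), HAGH (0.61 ± 0.06, q = 1.3e-09) and PARK7 (0.33 ± 0.07, q = 5.08e-05). It held less KLK3 (log2 -0.83 ± 0.05, q = 7.69e-15) and TXNIP (log2 -0.54 ± 0.1, q = 1.28e-05). HMOX1 was higher in C4-2 (log2 1.96 ± 0.13, q = 4.58e-13). ETV1 (0.534 ± 0.163 against 1390 ± 67.5 CPM, log2 -11.33 ± 0.28, q = 7.25e-23), PCAT14 (0.407 ± 0.186 against 954 ± 42.6 CPM, log2 -11.17 ± 0.25, q = 9.39e-24) and HGF (0.0758 ± 0.0749 against 186 ± 6.18 CPM, log2 -11.15 ± 0.18, q = 6.64e-27) were MDA-Pca-2b transcripts. GALC stood at 17.6 ± 1.51 CPM in C4-2 and at no count in MDA-Pca-2b, at least 386-fold higher, and KCNN4 at 15.7 ± 1.54 CPM in MDA-Pca-2b and at no count in C4-2, at least 411-fold lower. MDA-Pca-2b markers stood at 0.21 to 0.57% of their own level in C4-2 libraries, and C4-2 markers at 0.084 to 0.28% in MDA-Pca-2b libraries, so the fold of such genes also depends on stray reads.

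By list, 3 of 17 luminal markers were higher in C4-2, 11 were lower and 3 were not called (adjusted p = 0.000236 downward; adjusted p = 0.114 with an estimated correlation). Lower markers include KRT19 (14.6 ± 0.877 against 422 ± 19.9 CPM, log2 -4.85 ± 0.07, q = 1.46e-27) and ACP3 (10.8 ± 0.208 against 187 ± 14.9 CPM, log2 -4.11 ± 0.07, q = 1.2e-26). Of 6 basal markers 5 were lower and 1 was not called (adjusted p = 0.0113; adjusted p = 0.174 with an estimated correlation). KRT15 stood at 0.103 ± 0.0806 against 13.2 ± 1.48 CPM (log2 -6.94 ± 0.24, q = 9.86e-20) and KRT14 at 0.595 ± 0.305 against 12 ± 1.02 CPM (log2 -4.32 ± 0.24, q = 3.14e-15). All 3 neuroendocrine markers were higher in C4-2 (adjusted p = 0.00477; adjusted p = 0.134 with an estimated correlation). They include SYT4 (80.5 ± 4.72 against 2.72 ± 0.52 CPM, log2 4.89 ± 0.13, q = 2.23e-22) and DDC (25.6 ± 1.57 against 6.38 ± 0.634 CPM, log2 2.01 ± 0.1, q = 1.01e-15), which overlaps FIGNL1. Of 29 androgen-responsive genes 16 were higher, 10 lower and 3 not called (adjusted p = 0.0102 upward; adjusted p = 0.231 with an estimated correlation). MAF (16.5 ± 0.124 against 0.696 ± 0.053 CPM, log2 4.55 ± 0.17, q = 8.36e-19) and GNMT (20.8 ± 1.38 against 1.71 ± 0.1 CPM, log2 3.6 ± 0.15, q = 1.31e-17), which overlaps PEX6, were higher. Of 33 immediate early genes 6 were higher, 23 lower and 4 not called (adjusted p = 0.00939 downward; adjusted p = 0.78 with an estimated correlation). EGR1 stood at 1.1 ± 0.361 against 63.5 ± 7.61 CPM (log2 -5.85 ± 0.45, q = 4.41e-12).

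Other lists were not called between the lines. Of 18 detoxification genes 10 were higher, 5 lower and 3 not called (adjusted p = 0.68). LDHD, a lactate dehydrogenase that acts on the product of the glyoxalases, was higher in C4-2 (41.8 ± 1.39 against 1.2 ± 0.418 CPM, log2 5.09 ± 0.13, q = 1.82e-22). ALDH7A1 (0.333 ± 0.197 against 129 ± 6.56 CPM, log2 -8.58 ± 0.13, q = 1.47e-27) and AKR1C2 (0.498 ± 0.139 against 16.2 ± 0.987 CPM, log2 -5.01 ± 0.17, q = 4.5e-20) were lower. Of 28 NRF2 targets 11 were higher, 13 lower and 4 not called (adjusted p = 0.692), with ME1 (104 ± 1.9 against 0.172 ± 0.157 CPM, log2 9.24 ± 0.19, q = 1.55e-24) and EPHX1 (384 ± 14.7 against 31.1 ± 1.12 CPM, log2 3.63 ± 0.06, q = 3.03e-26) higher. Of 24 glycolysis genes 9 were higher, 11 lower and 4 not called (adjusted p = 0.68), with LDHB at 47.3 ± 5.95 against 0.0725 ± 0.0916 CPM (log2 9.18 ± 0.23, q = 4.84e-23). Of 29 heat shock genes 15 were higher, 9 lower and 5 not called (adjusted p = 0.68). HSPA1A alone gave -5.39 ± 0.15 (2.85 ± 1.36 against 120 ± 3.33 CPM, adjusted p = 7.18e-22), while its sum with HSPA1B gave -1.1 ± 0.08 (89.5 ± 4.98 against 191 ± 5.7 CPM, adjusted p = 5.55e-12). Of 14 fatty acid synthesis genes 7 were higher, 5 lower and 2 not called (adjusted p = 0.218), with FADS2, which overlaps FADS1, at 981 ± 41.2 against 16.6 ± 1.35 CPM (log2 5.89 ± 0.07, q = 1.4e-29). Of 10 epithelial-mesenchymal genes 5 were higher, 4 lower and 1 not called (adjusted p = 0.848). SNAI2 (5.73 ± 0.154 against 0.0286 ± 0.0248 CPM, log2 7.32 ± 0.38, q = 1.14e-15) and VIM (28 ± 2.96 against 0.965 ± 0.883 CPM, log2 4.86 ± 0.28, q = 6.8e-15) were higher and TWIST1 (0.179 ± 0.136 against 32.3 ± 1.03 CPM, log2 -7.46 ± 0.21, q = 7.28e-22) lower. Of 8 receptors of glycated protein 2 were higher, 5 lower and 1 not called (adjusted p = 0.673), with AGER at 3.18 ± 0.83 against 7.3 ± 1.35 CPM (log2 -1.21 ± 0.2, q = 5.41e-06). Of 2 leukocyte markers 1 was higher and 1 lower (adjusted p = 0.68), the latter HLA-DRA (0.648 ± 0.429 against 1450 ± 12.8 CPM, log2 -11.12 ± 0.31, q = 7.06e-22).

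For the rest, higher, lower and not called members in C4-2 were 5, 22 and 6 of the ATF4 list (adjusted p = 0.073), 13, 9 and 2 of the unfolded protein response (0.68), 5, 7 and 3 of NF-kB (0.68), 8, 8 and 8 of p53 (0.989), 5, 4 and 1 of glucose-sensing (0.68) and 3, 12 and 4 of hypoxia (0.222). They were 8, 12 and 4 of cholesterol synthesis (8 and 13 over the list alone; 0.68), 15, 5 and 4 of S phase (0.161), 13, 5 and 4 of G2 and mitosis (0.107), 22, 3 and 6 of the proteasome (0.17) and 12, 4 and 2 of interferon (0.121). They were 4, 5 and 4 of mitochondrially encoded transcripts (0.806) and 45, 12 and 8 of ribosomal proteins (0.222). Of 6 metallothioneins 4 were higher and 2 lower (0.68), and of 5 fibroblast markers 4 were higher and 1 lower (0.395). Signs of median, mean and test differed for the detoxification, receptor, NRF2, unfolded protein response, p53, glycolysis, metallothionein and epithelial-mesenchymal lists.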

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

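Tests chosen only after the result was seen are those of TXNIP and ARRDC4, of the length and GC correction and of MDA-Pca-2b reads for C4-2 7 mM replicate 3, all tests of MDA-Pca-2b transcripts in a C4-2 library, the length and GC test of the shared covariance, and the division of the splits of the difference into those that keep and those that break a line's groups.

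The methylglyoxal effects of the lines differ by the test of the difference itself in 2561 genes. Of 100 drawn splits of the libraries within each line, 6 (the real one included) called as many genes, with up to 6703. Counts this large point to a structure of the samples, here the treatment groups, whose effects stay in regrouped libraries. Chance is not excluded, as this count cannot test it. In 14 of the other splits the groups of 1 or both lines were kept or mirrored. All 5 with as many genes did so for MDA-Pca-2b. In 85 splits the groups of both lines were broken, which puts the effects into the spread, and the highest count was 1.

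Among the named genes, some of them chosen for this difference, 57 of 89 differ between the lines (14.6% of all tested), with log2 values given as C4-2 minus MDA-Pca-2b. The change was lower in C4-2 for the metallothioneins MT1G -6.02, MT1F -2.5 and MT2A -2.31 and, on the heat shock list, RGS2 -2.58, HSPA1A -2.46, HSPA6 -2.2, HSPA1B -2.04 and DNAJB4 -1.52. It was lower as well for the glucose-sensing genes TXNIP -2.3, ARRDC3 -1.87 and ARRDC4 -1.14. Early genes were EGR2 5.82, EGR1 4.8, EGR3 4.3, JUN -1.55 and DUSP8 -0.92. Stress and death genes were ATF3 -1.73, BBC3 -1.71, HMOX1 -0.93, MAFG -0.59, GDF15 0.54 and SLC7A11 0.43. Genes of the unfolded protein response were ERN1 -0.79, SEL1L 0.6 and HSP90B1 0.52. Androgen and luminal genes were ZBTB10 -1.37, TMPRSS2 -0.71, C1orf116 -0.69, FOXA1 -0.55, HOXB13 -0.21 and KLK3 0.22. Cell cycle genes were PLK1 -0.55, CCNF -0.36, GINS1 0.5, PCNA 0.47, CCNA2 0.35 and CLSPN 0.32. Metabolic genes were SREBF1 -0.41, VEGFA -0.37, ELOVL6 0.69, SLC16A1 0.6 and LSS 0.24. Immune, migration and ribosomal genes were ITGA5 -0.94, BIRC3 1.38, RPL39 0.43 and VIM 4.87. Others named for their size of change were MIR646HG -4.69, DLX5 -2.74, TMEM150C -2.53, ROCK1P1 -1.54, TUBA1A -1.53, INAVA -0.6, PTPRM 4.97, ZNF215 4.21, FAM171B 4.01, GAS6-AS1 0.96 and SULT1A1 0.88. The calls of PTPRM, ZNF215 and TMEM150C end without single libraries (values above).

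Lists differ between the lines as well. For methylglyoxal these are metallothioneins (adjusted p = 4.26e-31; adjusted p = 2.44e-05 with an estimated correlation), heat shock (1.17e-13; 0.139), glucose-sensing (6.81e-08; 0.00253), S phase (5.31e-07; 0.189), unfolded protein response (0.000121; 0.142), ribosomal proteins (0.00013; 0.946), mitochondrial transcripts (0.0262; 0.81) and p53 (0.0332; 0.247). For 25 mM glucose they are ribosomal proteins (3.84e-16), mitochondrial transcripts (1.66e-07), immediate early genes (6.83e-06), proteasome (1.98e-05) and heat shock (0.0111), each at 0.854 with an estimated correlation. For the 25 mM difference edgeR called 0 genes (2450 unadjusted, 210 by DESeq2), so all 100 of 100 splits gave as many, with up to 41.

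The other comparisons are of 3 against 3 libraries, whose 10 splits are too few for a share under 0.05. Broken groups put any effect into the spread here too. Methylglyoxal in C4-2 gave 4033 genes (1 of 10 splits as large; highest other 70) and in MDA-Pca-2b 6121 (1 of 10; highest other 0). The lines at 7 mM gave 13099 (1 of 10; highest other 0). For 25 mM glucose in MDA-Pca-2b 2 of 10 splits gave at least the 4 genes, with up to 5. In C4-2 3 of 10 gave at least the 3 genes, with up to 269, several times the real count, in the split that joins 7 mM replicates 1 and 2 with 25 mM replicate 3, which points to a structure of the samples.

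C4-2 replicate 3 at 7 mM glucose stands apart from replicates 1 and 2. Over 500 genes its median position was 0.94 between these (0) and 25 mM glucose (1), which met the value written for a library from a 25 mM culture, but methylglyoxal libraries lay at 1.1 to 1.43, so the scale is not specific to glucose. In a fit with replicate 3 as its own group, whose spread comes from the other groups, TXNIP stood at 28 CPM, against 22.3 and 26.1 in its group and 39.2 to 47.1 at 25 mM (25 mM higher by log2 0.58 ± 0.13), and ARRDC4 at 16.6 CPM, against 16.3 and 17.7 and 20.4 to 21.2 (0.31 ± 0.11). By these 2 genes a library from a 25 mM culture is not supported. Length and GC content accounted for 29.2% of the variance of its deviation, but also for 30.1 and 34.7% in MDA-Pca-2b 7 mM replicates 1 and 2. In genes over 8 CPM 1805 were called for 25 mM glucose without this library, against 584 with that trend removed. The 29.2% and the 584 lie between the values set for and against this explanation. Reads of MDA-Pca-2b cells are not supported, since its marker level was 1.01 times that of the higher replicate (counting interval 0.909 to 1.13), just over the bound of 1 but below the 2 set for this explanation. A technical trend stays open, as does a difference between cultures (not tested).

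Transcripts of MDA-Pca-2b cells stand at 0.57% of their own level in the C4-2 library of 25 mM replicate 2. Of 38 markers 34 were higher there than in both other replicates (89.5%, just under the 90% set for stray reads), and their levels followed those in MDA-Pca-2b (Spearman 0.88). Induction by glucose is not supported, since the lower of the other replicates stood at 0.749 times the highest 7 mM library. Marker thresholds were chosen after an earlier look at these libraries. A small share of MDA-Pca-2b reads may explain the pattern, but whether it came from cells, libraries or sequencing cannot be told.

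Fold changes of methylglyoxal and of 25 mM glucose go together in C4-2, with a covariance of 0.018 over 9633 genes. The lowest covariance with a 7 mM library left out was 0.0137, against at most 0.00387 in simulations and 0.00455 from the replicate spread. This cannot exclude a deviation shared by 7 mM replicates 1 and 2. Replicate 3 is not the source by this test, as the covariance without it was 0.0303. After removal of the length and GC trend it was 0.00713, between the simulated level and the value set against that explanation. A trend shared by libraries may thus account for part of it, and a response shared by both treatments remains a hypothesis.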

How the results depend on the processing

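Chosen after the data were seen were the length and GC corrections, the removal of genes of the other line, the 25 mM libraries as control for lists, named genes and the overlap of the lines, the lines at 25 mM for named genes, lists with a library left out, and the overlap within a line by RLE and by fits of 1 line. Of named genes and lists, RLE kept 228 of 228 on their side, the block 227 (TMEM150C lost, adjusted p = 0.0516), at least 1 CPM 175 of 175, DESeq2 171 (1 weaker), no filter 171 (1 weaker, 2 stronger), leaving out a library 1581 (62 weaker, 3 stronger) and the removal of genes of the other line 137 of 137. The 25 mM control kept 138 (18 weaker), fits of 9 and 6 samples 104 (3 weaker) and 102 (4 weaker), the lines at 25 mM 32 (TXNIP lost, 0.052), and an estimated correlation 7 lists (45 weaker). The cause of the moves below was not tested, unless fewer genes or samples account for it.

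Genes called at 25 mM glucose in C4-2 (3) were 7 by RLE or with the block and 354 with no filter (142 higher, 212 lower). DESeq2 gave 460 (1 of the 3 kept, losses not in the tally above). They were 1 in genes over 8 CPM with or without the length and GC trend, and 5 with the trend removed in all genes. Without 7 mM replicate 3, genes over 8 CPM gave 1805, or 584 with the trend removed. In MDA-Pca-2b (4) they were 22 with no filter, 1 at a log2 fold change of at least 1, 2 in fits of 9 or of 6 samples and 7 by DESeq2. The difference (0 by edgeR, 2450 unadjusted) was 164 with no filter and 210 by DESeq2. A log2 fold change of at least 1 left 270 genes for methylglyoxal in C4-2, 769 in MDA-Pca-2b, 248 for their difference and 6028 between the lines. Methylglyoxal in C4-2 (4033) gave 1666 against the 25 mM control, 2602 with the trend removed in genes over 8 CPM (3837 uncorrected), 2570 in all genes and 2727 in all genes by the trend of those over 8 CPM. The overlap of the lines (2246) was 1292 against the 25 mM control. The overlap within C4-2 (1) was 3 by RLE, 281 by DESeq2 and 2 in fits of 9 samples, and within MDA-Pca-2b (2) it was 1 in fits of 9 samples.

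Lists called, in the order methylglyoxal in C4-2, in MDA-Pca-2b, 25 mM in C4-2, in MDA-Pca-2b, the 2 differences and the lines, were 12, 10, 6, 6, 8, 5 and 5, and with an estimated correlation 1, 4, 0, 0, 2, 0 and 0. Fry called 15, 15, 0, 0, 8, 0 and 26 in this order. With 1 library left out, genes called ranged from 2277 to 4730, 5273 to 5598, 1 to 1447, 2 to 5, 1991 to 3121, 0 to 905 and 12666 to 12871 in the same order, and lists from 12 to 16, 9 to 11, 4 to 9, 3 to 6, 6 to 9, 4 to 7 and 5 to 6. The extremes of 25 mM glucose in C4-2 came without 7 mM replicate 1 or 3.

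Single genes with changes near 0 turned in sign with no call. GLO1 with methylglyoxal in MDA-Pca-2b was 0.02 with no filter and in fits of 9 or 6 samples, 0.1 against the 25 mM control and -0.02 (without 7 mM replicate 1) to 0.03 without single libraries, and its difference -0.04 against the 25 mM control. HAGH there was 0 with no filter or 6 samples, 0.01 with 9 samples and -0.06 to 0.03 without single libraries, and PARK7 -0.04 to 0.06. Against the 25 mM control mitochondrial transcripts in C4-2 (adjusted p = 0.384) and ribosomal (0.453) and mitochondrial (0.608) differences turned. Correlations of libraries from different groups passed 0.1 in 1 of 9 pairs of the same replicate number and 7 of 18 others in C4-2, and in 5 of 9 and 3 of 18 in MDA-Pca-2b (same number -0.28 to 0.35 over both). Not every pair passed, so the numbers were not taken as pairs. No scaling moved the median of all genes by over 0.1. Depth limits genes near the floor of 3 counts, such as ZNF215 and MIR646HG.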

Other observations

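Gene Ontology tests, count ratios and the choice of list members in this part came after the data were seen, while the calls of list members are planned ones. Of 1302 Gene Ontology terms (15 to 300 genes) the list test called 25 for methylglyoxal in C4-2 and 31 in MDA-Pca-2b. It called 32 for their difference, and 24, 31 and 53 for 25 mM glucose. With an estimated correlation the same test called 0 in each, so no term is named.

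List members called in both lines in opposite directions with methylglyoxal were BIRC3 (0.97 in C4-2, -0.41 in MDA-Pca-2b), SPARC (0.83, -1.86), GPAM (0.26, -0.32), SLC16A1 (0.23, -0.37), HSP90B1 (0.25, -0.27), CDC20 (-0.3, 0.16), TMPRSS2 (-0.28, 0.43), HSPA1B (-0.75, 1.29) and HSPA1A (-1.34, 1.12). For genes with 0 to 3 counts in a group, ratios of counts with methylglyoxal over 7 mM glucose were 0.0297 (counting interval 0.00352 to 0.112) for VIM in MDA-Pca-2b and 19.7 (3.03 to 829) for FAM171B in C4-2. PTPRM was at least 4.77-fold lower and ZNF215 at least 1.84-fold lower in MDA-Pca-2b, against a floor of 3 counts over the group, and MIR646HG at least 2.79-fold higher.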
